A study of Rattus norvegicus with 4 samples.

How the data were processed

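Single-cell RNA sequencing was done on cells from sciatic nerve and dorsal root ganglion of Sprague Dawley rats aged 1 day or 8 weeks. The labels give 4 groups with 1 library each. The deposited values were UMI counts (unique molecular identifiers, 1 per captured transcript) in 1 matrix of 25399 genes and 41444 cell barcodes, with 75493450 entries and 336170988 UMIs. Per the file headers the counts came from Cell Ranger 3.1.0. The submitters' processing notes also name CASAVA 1.8, Seurat and the genome build Rnor_6.0, without saying what each was used for. The culture protocol in the labels describes primary Schwann cells kept in medium with serum, and the labels do not say whether the sequenced cells had been cultured.

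Each barcode ended in a number from 1 to 4. None of the labels or files used here ties that number to a tissue or an age, so the libraries are called library 1 to library 4, and none was assigned to a group. No comparison between tissues or between ages was made. Every contrast was computed between cell classes or clusters inside 1 library, and values from several libraries are given one by one or as a range with a median, not as replicates. Because each group had 1 library, no test between groups was possible. The 4 libraries come from 4 different groups and were not tested as replicates, so no p-values are given. All intervals are exact 95% intervals (Clopper-Pearson for shares and for ratios of counts) and cover counting error only. For a count of 0, the share it allows is given as 3 counts of the total.

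Barcodes were kept with at least 500 detected genes and at most 20% mitochondrial UMIs. Doublets called by the Scrublet method (scanpy 1.11.5) in each library were removed. The caller found 395 doublets in library 1 (4.02% of those past the other filters), 0 in libraries 2 and 3, and 3 in library 4, so doublets were hardly removed outside library 1. Of the barcodes, 32777 were kept as cells and 8667 were removed. Counts were scaled to 10000 per cell and logged. The 2000 most variable genes were used without the genes of the fixed lists and without mitochondrial and ribosomal protein genes. With 30 principal components and 15 neighbours, a shared-neighbour graph was clustered by the Leiden method at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), which gave 43 clusters. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.

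Clusters were named "X-like" from markers of 17 cell classes. Of 112 marker genes, 101 were found in the gene table. A class needed at least 3 markers, each at 2 or more times the median of the cluster means and detected in at least 10% of the cluster's cells. Among such classes the highest score gave the name. The score was the mean level of a class's markers, each relative to the cluster where it was highest. Cluster 11 was thus named fibroblast-like at 0.36, though cartilage or bone, with 2 markers, scored 0.379. A cluster stayed unnamed where its 10 leading genes held more markers of another class, or where it had low depth and no marker among them. Depth was judged here against the median of the cells' own library. Clusters 5 and 25, at 0.204 and 0.113 of it, stayed unnamed for low depth. Clusters 3, 7 and 13, called low-depth below for their few UMIs, were at 0.548, 0.819 and 0.721 and were not held back for depth. This naming rule was set after the clusters had been seen. It named 38 clusters, and 5 clusters with 3330 cells stayed unnamed (10.2% of cells). No cluster could be named satellite glia-like: cluster 10 scored highest for that class, with Fabp7 and Slc1a3 among its markers, but was led by Tyrp1, a melanocyte marker. The contrast planned for satellite glia is therefore given for cluster 10, by number. No cluster was named B cell-like, mast cell-like, skeletal muscle-like, adipocyte-like, cartilage or bone-like, or melanocyte-like.

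The 12 gene lists covered myelin proteins, cholesterol synthesis, immature and repair Schwann cell genes, myelination regulators, neurotrophic and growth factors, basement membrane and matrix, axon guidance, Hox genes, cell cycle, immediate early and stress genes, antigen presentation, and chemokines and cytokines. They held 178 genes, of which 174 were found (Pou3f1, Hspg2, Ccnb2 and Ier2 were not). The markers, lists, filters, planned contrasts, named-gene rule and 14 of the 20 alternatives were chosen before the data were examined. The plan held the contrast with satellite glia-like cells only if that class could be named. It listed levels across all named classes, but no contrasts with endothelial-like, macrophage-like, neuron-like or mural-like cells. In each contrast, UMIs were summed per side and library, and the log2 ratio of library-size-scaled counts (CPM, the share of a side's UMIs on a fixed scale) was taken with a floor of 3 UMIs per side. A gene needed 20 summed UMIs on one side, a side needed 20 cells, clusters with fewer cells in a library were left out of contrasts between Schwann-like clusters, and a list needed 3 genes. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on expression in 20 bins. Named genes were, per list, up to 4 with the largest absolute log2 ratio among those going the same way in every library where they could be measured. Results of some single genes are not reported here. For cell cycle shares, each cell was thinned to 2000 UMIs in 1 random draw, made separately for each class, cluster and alternative, and counted if it held at least 1 UMI of Mki67, Top2a, Cdk1, Cenpf or Birc5, and cells under 2000 UMIs were left out.

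The contrast was tested on simulated counts with the depths of Schwann-like over fibroblast-like cells. These counts were drawn for each gene independently with counting error only, which is the error the intervals assume. They cannot tell how intervals or percentiles fare with variation between cells or with genes that vary together. In libraries 1 to 4, with 12427, 8538, 10614 and 12877 genes, a simulated 2-fold change was recovered for 46.8%, 91.3%, 86.7% and 92.3% of changed genes. A 4-fold change was recovered for 78.8%, 98.9%, 98.1% and 100% of them. Unchanged genes had an interval away from 0 in 3.16%, 5.54%, 4.08% and 4.34% of cases. Of random lists, 6.5%, 6%, 9% and 3% fell outside the central 95% of percentiles, and an implanted list reached the percentile 100 in each library.

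Alternatives were a mitochondrial limit of 10%, a minimum of 200 genes, doublets kept, resolutions 0.4 and 1.2, and clustering with the list genes. Others were CPM without mitochondrial, ribosomal protein and haemoglobin genes, minimums of 5 and 100 summed UMIs, the mean of each cell's CPM, and cells thinned to 2000 UMIs. For the cell cycle shares, no thinning, thinning to 1000 UMIs and a minimum of 2 UMIs were tried. Chosen after seeing the data were removal of the top 6% of doublet scores, the Schwann-like class without cluster 13 or without cluster 9, the neuron-like class without its low-depth clusters or with the unnamed clusters that scored highest for neurons, and cell cycle shares without Birc5.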

Results

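The 4 libraries held 10542, 10087, 10256 and 10559 barcodes and 74425958, 81920125, 97572003 and 82252902 UMIs, in the order of libraries 1 to 4. After filtering, 9433, 8426, 6473 and 8445 cells remained, with median depths of 6504, 1645.5, 4639 and 7554 UMIs. The labels put 1 library in each of 4 groups (sciatic nerve and dorsal root ganglion, each at 1 day and at 8 weeks), and the barcodes do not say which library is which. The series title asks how Schwann cells, the glia that wrap peripheral axons, differ between ganglion and nerve. That comparison was not made here, and the values below describe Schwann-like cells against other cells of their own library.

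Schwann-like cells, named by markers that include Sox10, S100b, Erbb3 and Cdh19, made up 3.31% of cells in library 1 (95% interval 2.96% to 3.69%), 13.8% in library 2 (13.1% to 14.5%), 13.5% in library 3 (12.6% to 14.3%) and 77.5% in library 4 (76.6% to 78.4%). Fibroblast-like cells (Col1a1, Dcn, Pdgfra) made up 65.9%, 5.03%, 22.7% and 13.6% of cells in libraries 1 to 4. Neuron-like cells (Snap25, Nefl, Prph) made up 49.3% of library 2 and 25.6% of library 3. Without the low-depth clusters 3 and 7 the share of library 2 was 5.07%. This leaves out cluster 29, which scored highest for neurons but stayed unnamed for leading genes of another class. It held 269 cells (3.19% of library 2) with a median of 56472 UMIs. With the low-depth cluster 5, which also scored highest for neurons but stayed unnamed, the share of library 3 was 49.8%. In library 1 there were 0 neuron-like cells of 9433, which allows a share of up to 0.0318%, and library 4 held 1. Macrophage-like cells reached 22.3% in library 1 and lay between 1.28% and 2.31% in the other libraries. Endothelial-like cells made up 1.35%, 8.36%, 3.91% and 0.947%. Perineurial-like cells, the sheath cells of nerve fascicles, made up 4.31% of library 1 and 0.237% of library 2. The remaining named classes were mural-like (765 cells), T or NK cell-like (299), neutrophil-like (218) and erythroid-like (117). The Schwann-like share of library 2 rested on cluster 13, a cluster of 922 cells with a median of 1187 UMIs, and was 2.85% without it. At a mitochondrial limit of 10% the share was 1.94% in library 1 and 2.63% in library 2.

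Set against fibroblast-like cells of the same library, Schwann-like cells carried the myelin program at far higher levels in every library. The median log2 ratio of the myelin protein list was 7.15, 5.72, 5.86 and 3.78 in libraries 1 to 4. Of the measured members, 12 of 12, 13 of 13, 12 of 12 and 12 of 13 were higher in Schwann-like cells by their intervals, and 1 was lower in library 4. Mbp, a protein that compacts the myelin membrane, had log2 ratios from 4.08 to 8.59 with a median of 7.37 over the 4 libraries. Mal (4.23 to 9.67) and the adhesion protein Mag (4.55 to 11.05) went the same way. Without cluster 13 the median of the list over libraries moved from 5.79 to 6.49, and at a mitochondrial limit of 10% to 6.95.

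Genes of cholesterol synthesis, which supplies myelin membrane, were also higher. All 14 genes were higher in each of the 4 libraries, with list medians of 2.30, 1.74, 2.0 and 1.08. Hmgcs1, an early enzyme of the pathway, had log2 ratios from 1.14 to 2.51. Cyp51 (1.04 to 2.52) and Msmo1 (1.66 to 2.78) had similar ranges. These ratios were smaller than those of the myelin proteins, and every list median stood at the percentile 99.98 or above among random lists.

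Immature and repair Schwann cell genes had list medians of 3.08, 2.26, 1.65 and 2.96, each at the percentile 100. Higher were 9 of 11, 9 of 11, 9 of 12 and 10 of 13 members, and 1, 0, 3 and 3 were lower. Sox2, a transcription factor of immature glia, had log2 ratios from 4.42 to 9.60, the adhesion molecule Ncam1 from 2.97 to 7.92 and Gfap from 3.60 to 10.00. Olig1 could be measured in 1 library and was lower there (-5.94). Myelination regulators were higher by less, with list medians of 1.31, 1.2, 0.97 and 0.71. Higher were 7 of 9, 6 of 10, 7 of 10 and 7 of 10 of them, and 1, 1, 1 and 2 were lower. Among them the receptor Adgrg6 (3.01 to 5.87) and the transcription factors Zeb2 (2.08 to 2.27) and Pou3f2 (4.54 to 6.89, 3 libraries) were higher, and Nfatc4 was lower (-4.65 to -2.20).

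Chemokines and cytokines were mostly lower, with list medians of -0.92, -3.19, -3.45 and -2.26. Lower in Schwann-like cells were 8 of 12, 9 of 11, 9 of 9 and 8 of 12 members, and 3, 1, 0 and 3 were higher. The alarmin Il33 had log2 ratios from -6.69 to -4.20, Il6 from -5.29 to -3.45, Ccl7 from -5.19 to -2.65 and Ccl11 from -5.55 to -1.77. Growth factors had list medians of 0.66, -2.0, -1.40 and -2.05. In libraries 1 to 4, 7 of 17, 6 of 13, 4 of 16 and 4 of 19 were higher and 6, 7, 9 and 15 were lower. Igf1 (-7.73 to -2.08) and Igf2 (-8.43 to -2.77) were lower in all 4 libraries, while Gdnf was higher (3.40) and Lif lower (-4.31) in the 1 library where each could be measured. With a minimum of 5 UMIs the median of this list over libraries moved from -1.70 to -0.67.

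The basement membrane and matrix list was split. Its medians were -0.69, -1.90, 0.03 and -0.47, with 5, 4, 7 and 6 of 15 members higher and 8, 9, 7 and 8 lower. Fibronectin (Fn1, -7.20 to -5.03), versican (Vcan, -6.19 to -4.71), Postn (-4.67 to -0.75) and Col5a1 (-2.84 to -2.22) were lower in all 4 libraries. Axon guidance genes had medians of 0.50, -2.67, -1.59 and -1.56, with 5 of 18, 4 of 15, 3 of 16 and 5 of 18 higher and 7, 10, 9 and 11 lower. Sema3b was higher (2.31 to 5.23), and Sema3d (-7.95 to -4.12), Ntn1 (-8.07 to -1.39) and the semaphorin receptor Nrp1 (-4.06 to -3.04) were lower. With a minimum of 100 UMIs the axon guidance median over libraries moved from -1.57 to -2.57.

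The other lists did not go 1 way. Cell cycle genes had medians of 1.51, 2.0, -0.37 and 0.23, with 9 of 15, 10 of 12, 4 of 15 and 8 of 15 higher and 0, 0, 6 and 4 lower. Top2a (0.33 to 3.50), Cenpf (0.31 to 2.87) and Birc5 (0.95 to 2.75) were higher in all 4 libraries and Mki67 in 3 by its interval. These values rested on cluster 9, the Schwann-like cluster led by cell cycle genes, which had 7, 15, 75 and 930 cells in libraries 1 to 4. Without it, a comparison that takes dividing cells from 1 side only, the list medians were -0.17, 0.53 (3 genes), -2.38 and -2.06, and Top2a, Cenpf, Birc5 and Mki67 had medians of -4.39, -3.08, -1.66 and -3.08 over the libraries where they could be measured. Immediate early and stress genes had medians of 0.68, -0.19, -0.74 and -0.30 over 12 genes each, of which 9, 3, 1 and 4 were higher and 1, 7, 10 and 8 were lower. Fos was higher (0.14 to 1.34) and the phosphatase gene Dusp1 lower (-2.93 to -1.80). Antigen presentation genes had medians of -0.29, 0.12, -0.79 and -0.87, with 1 of 10, 3 of 7, 1 of 4 and 1 of 5 higher and 4, 3, 2 and 3 lower. The class I genes B2m (-1.14 to -0.34) and RT1-A1 (-1.95 to -0.23) were lower in all 4 libraries. Hox genes had medians of -0.04, -1.37, -1.94 and 0.26 over 6, 4, 7 and 9 genes, of which 0, 1, 2 and 4 were higher and 1, 2, 5 and 1 were lower. Hoxc10 was lower in 3 libraries (-1.89 to -1.51), and with a minimum of 5 UMIs the Hox median over libraries moved from -0.71 to -0.04.

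The median over all genes was 0.64, 0.17, 0.07 and 0.06 in libraries 1 to 4, and relative to it the library 1 medians of growth factors and of axon guidance were 0.01 and -0.15. In library 1, 312 Schwann-like cells were set against 6214 fibroblast-like cells. With sides so unequal, the floor of 3 UMIs could give a gene without any Schwann-like UMI a positive ratio. The list medians of library 1 can therefore be too high. In the ranges of Mag, Gfap, Olig1, Pou3f2, Nfatc4, Igf2, Sema3b, Sema3d, Ntn1, Ccl11 and Il6, at least 1 library had fewer than 3 UMIs on the lower side, where the floor was used.

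**Figure D1:**
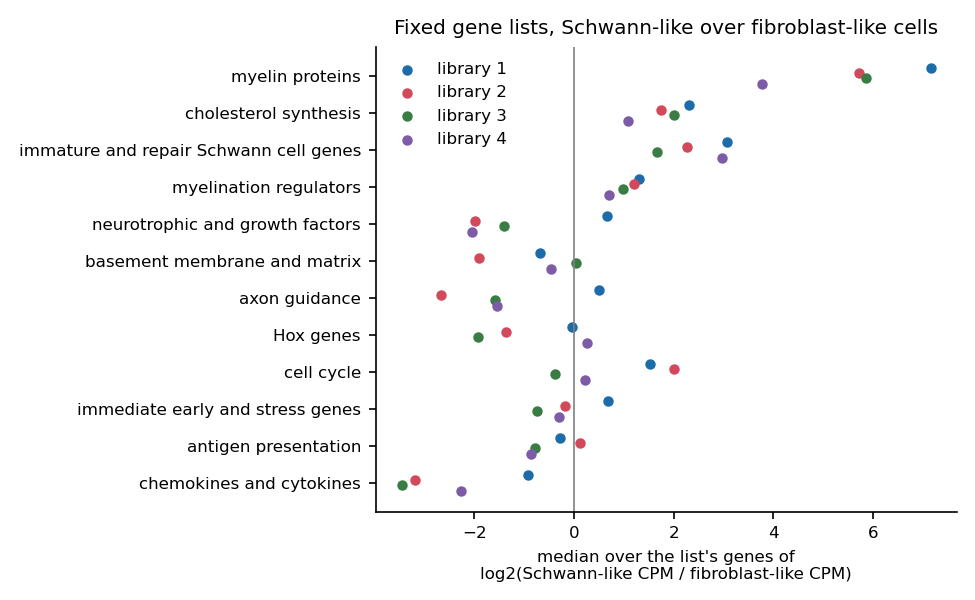
Each point is the median log2 ratio of CPM, Schwann-like over fibroblast-like cells, over the measured genes of a fixed list (vertical axis) in 1 library (colour), and the grey line marks 0. Myelin proteins lay between 3.78 and 7.15 and cholesterol synthesis between 1.08 and 2.30, while chemokines and cytokines lay between -3.45 and -0.92.

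Across all named classes, Schwann-like cells held the highest level of 11 of 12 myelin protein genes in every library. They also held the highest level of 4 of 14 cholesterol synthesis genes (Cyp51, Insig1, Msmo1 and Sc5d) and of 4 of 11 immature and repair genes (Sox2, Ncam1, Id4 and Gfap). Of 9 regulators, Egr2, a transcription factor that drives myelin genes, and Adgrg6 were highest there. Of 15 matrix genes, Col5a3 was highest in Schwann-like cells, at 538, 279, 648 and 2266 CPM against 229, 160, 342 and 1101 CPM in fibroblast-like cells, and Col5a1, Fn1, Sparc and Postn were highest in fibroblast-like cells. Sema3b was the only 1 of 16 axon guidance genes highest in Schwann-like cells in every library, and Efnb2 and Unc5b were highest in endothelial-like cells. Of 15 growth factors, Igf1 and Mdk were highest in fibroblast-like cells. These counts cover genes measured in all 4 libraries and the named classes present in each, so unnamed clusters were not ranked. In library 2, the unnamed cluster 10 was above Schwann-like cells in Cyp51 (1323 against 384 CPM) and Msmo1 (1148 against 449 CPM). It was also above them in Insig1, Sc5d, Ncam1, Gfap, Adgrg6 and Col5a3, and below them in Sox2, Id4, Egr2 and Sema3b.

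Cluster 10, which stayed unnamed, had 1016 cells in library 2 with a median depth of 9350 UMIs. It carried satellite glia markers that include Fabp7 and Slc1a3, and was compared with the 1162 Schwann-like cells of library 2. Mitochondrial genes made up 14.8% of the summed UMIs of cluster 10, against 8.55% in the Schwann-like cluster 13 and 9.15% in cluster 32. The median share per cell was 14.76% in cluster 10 (all libraries), 1.504% in cluster 13 and 8.29% in cluster 32. The summed share of cluster 13 was therefore far above that of its typical barcode. At a mitochondrial limit of 10% no cluster matched cluster 10, so the contrast could not be repeated there. All 13 myelin protein genes were lower in cluster 10, with a list median of -4.44. Among them were Pllp (-9.08), Cldn19 (-6.49), Gldn (-9.13) and Mag (-8.67), and the last 2 had 1 UMI each in cluster 10, where the floor was used. Cluster 32, with 220 cells, held most of the Schwann-like UMIs of these genes (1260 of 1343 for Pllp and 291 of 303 for Mag). Cholesterol synthesis went the other way, with a list median of 1.38 and 13 of 14 genes higher. Among these were the sterol enzymes Cyp51 (1.79), Dhcr7 (1.65) and Lss (1.63).

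Chemokines and cytokines were higher in cluster 10, with a list median of 1.2 and 7 of 10 members higher, among them Il6 (2.05), Ccl2 (1.82) and Ccl7 (1.62), while Cxcl14, also with 1 UMI there, was lower (-5.23, with 26 of the 28 Schwann-like UMIs in cluster 32). Of the matrix list 8 of 15 were higher and 4 lower (median 0.46), with Tnc at 2.38 and Postn at -1.62. Of 14 cell cycle genes 11 were lower (median -4.15), among them Top2a (-6.38) and Mki67 (-5.54), but the 15 cells of cluster 9 held 91.6% of the Schwann-like UMIs of 5 such genes. Without these cells the median was -0.54 over 8 genes, with 3 lower and 0 higher. The immature and repair list was divided (median -0.07, with 4 of 12 higher and 6 lower): Ncam1 was higher (1.21) and Gap43 (-2.10), Ngfr (-1.77) and L1cam (-1.13) were lower. Growth factors (-0.46, with 4 of 11 higher and 5 lower) held Vegfa at 1.81 and Cntf at -4.01, where cluster 32 held 263 of 288 Schwann-like UMIs. Axon guidance (-0.06, with 3 of 10 higher and 5 lower) held Slit2 at -2.43 and Nrcam at -2.11, both carried by cluster 32: cluster 13 had 1.15 and 5.76 CPM, below the 2.44 and 6.23 CPM of cluster 10. Antigen presentation (-0.43, with 2 of 7 higher and 4 lower) held Cd74 at -3.01. Regulators (-0.23, 3 of 9 higher and 4 lower) and immediate early genes (-0.16, 3 of 12 higher and 6 lower) had small medians, and Hox genes had a median of -1.06, with 1 of 5 higher and 2 lower.

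The median over all genes in this contrast was -0.25, relative to which the cholesterol list stood at 1.63 and the myelin list at -4.19. Cluster 13, which gave 922 of the 1162 Schwann-like cells, was led by Fabp7, a satellite glia marker that cluster 10 also carried. Without it the myelin median was -5.80, the cell cycle median was -5.39, the growth factor median turned to 0.42 and the antigen presentation median to 0.19. The growth factor median also turned with a minimum of 100 UMIs (1.31), with thinned cells (1.11) and at resolution 0.4 (0.22), and the cell cycle median was -2.06 with thinned cells. The small medians of the immature, regulator, axon guidance and immediate early lists changed sign under at least 1 setting.

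Inside the Schwann-like class, cluster 6 held the highest myelin levels in libraries 1, 3 and 4. Its myelin protein list summed to 114268, 149187 and 29293 CPM in these libraries, against 14047 CPM in cluster 30 of library 1, 23664 in cluster 16 of library 3 and 11817 in cluster 1 of library 4. In library 2, cluster 32 had 121062 CPM and cluster 13 had 5185. Against the other Schwann-like clusters with at least 20 cells in its library, which in library 1 was cluster 30 alone, cluster 6 had myelin list medians of 2.88, 2.31 and 2.5, with 11 of 12, 11 of 11 and 13 of 13 members higher. Prx (2.04 to 6.11), a protein of the myelin sheath, and the tight junction gene Cldn19 (1.65 to 4.73) were higher in all 3 libraries. The clusters were picked by these levels, so the myelin values are descriptions.

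The median over all genes was -0.27, -0.22 and -0.03 in these contrasts. Genes of immature cells had list medians of -1.18, -0.22 and -0.81 in cluster 6, with 5 of 9, 5 of 11 and 9 of 12 members lower against 0, 1 and 2 higher. Ncam1 (-3.67 to -1.05), L1cam (-3.28 to -2.07) and the neurotrophin receptor Ngfr (-2.85 to -2.02) were lower in all 3 libraries. Growth factors (-1.23, -0.59 and -0.69) were lower in 3 of 6, 3 of 7 and 9 of 16 members and higher in 1, 0 and 5, with Ptn from -4.85 to -0.70. Matrix genes (-0.68, -0.74 and -0.59) were lower in 7 of 12, 10 of 15 and 13 of 15 members and higher in 2, 0 and 1, with Lamc1 from -1.61 to -0.61. Axon guidance genes (-1.53, -0.39 and -1.05) were lower in 2 of 3, 3 of 7 and 12 of 16 members and higher in 0, 2 and 2, although Nrcam was higher in 2 libraries (2.04 to 2.62). Cell cycle genes were lower in 9 of 13 members in library 3 (-1.62) and in 15 of 15 in library 4 (-3.86), with Mki67 at -2.61 and -5.16. Without cluster 9 on the other side the medians were 0.02 (6 genes) and -0.86, and Mki67 was at -1.38 in library 4.

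Cholesterol synthesis was divided, at 0.26, 1.55 and 0.05, with 3 of 12, 13 of 14 and 6 of 14 genes higher and 2, 0 and 4 lower. Immediate early and stress genes were at -0.39, -0.05 and -0.78, lower in 6, 4 and 12 of 12 and higher in 3, 2 and 0, with Hspa1a from -0.94 to -0.76. Chemokines were at -1.46 in library 1 and -0.51 in library 4, lower in 4 of 6 and 5 of 11 and higher in 0 and 1, with Ccl2 from -5.01 to -1.26. Regulators were at 0.20, -0.42 and -0.06, with 2 of 6, 1 of 9 and 4 of 10 higher and 0, 1 and 4 lower, and Ndrg1 was higher in all 3 libraries (0.81 to 2.49). Antigen presentation was at 0.01, -0.57 and -0.33, with 0 higher and 3 of 7, 2 of 3 and 2 of 5 lower, among them B2m (-0.66 to -0.37). Hox genes were at -0.07 and -0.08 in libraries 3 and 4, with 0 higher and 0 of 3 and 1 of 9 lower. At a mitochondrial limit of 10%, the Schwann-like cluster of library 4 with the highest myelin level was used, without matching it to cluster 6. Its medians were 0.77 for cholesterol synthesis, 0.14 for regulators and -0.84 for Hox genes. Cluster 6 had 55 cells in library 1 and 37 in library 3, and 1387 in library 4, and the floor was used in at least 1 library for Ngfr, L1cam, Ptn, Mki67 and Ccl2.

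In library 2, cluster 32 (220 cells) was compared with the low-depth cluster 13 alone, since clusters 9 and 16 had 15 and 5 cells there. Cluster 13 scored 0.38 for Schwann cells and 0.339 for satellite glia. At resolution 0.4, 99.8% of its cells joined the cluster matched to cluster 10. The values below therefore cannot be read as states of Schwann cells alone. The median over all genes was -0.33. The myelin list median was 5.12, with 13 of 13 higher, among them Cldn19 (6.5), Prx (6.41) and Gldn (6.35). The immature list median was -1.20, with 9 of 11 lower, among them Ncam1 (-2.93) and Gfap (-2.06). The growth factor list median was -1.78, with 5 of 9 lower and 1 higher: Ptn was at -3.74 and Mdk at -3.33, while Cntf, a neurotrophic cytokine, was at 4.54. Chemokines were lower in 4 of 5 members (median -2.37), among them Il33 (-3.94, with 0 UMIs in cluster 32) and Ccl2 (-3.35), while Cxcl14 was higher (4.26, with 2 UMIs in cluster 13). Antigen presentation genes were lower in 5 of 6 members (-0.99), among them Cd74 (-2.44). Regulators (-0.26, with 3 of 9 higher and 1 lower) held Ndrg1 at 3.08 and Egr2 at 1.41. Cholesterol synthesis (-0.24, 3 of 14 higher and 7 lower), matrix (-0.31, 5 of 13 higher and 3 lower), axon guidance (0.20, 3 of 6 higher and 3 lower) and immediate early genes (-0.09, 5 of 12 higher and 6 lower) went both ways.

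Cells with at least 1 UMI of Mki67, Top2a, Cdk1, Cenpf or Birc5, 5 genes of cell division, made up 3.46% of Schwann-like cells in library 1 (95% interval 1.51% to 6.71%), 4.29% in library 2 (2.68% to 6.49%), 13.4% in library 3 (11% to 16.2%) and 19.5% in library 4 (18.5% to 20.5%), all thinned to 2000 UMIs. In cluster 9, led by Cenpf and Top2a, 91.9% of cells in library 3 and 93.5% in library 4 were counted. These were 57 and 843 cells, against 91 and 1247 cells counted in the whole Schwann-like class of these libraries, in separate random draws. In the other large clusters the shares were 8.45% in cluster 1, 4.28% in cluster 6 (library 4), 5.75% in cluster 16 and 2.11% in cluster 13. In cluster 30 it was 0 of 175 cells, which allows a share of cells with a UMI of up to 1.71%. Fibroblast-like cells were at 1.72%, 0.508%, 12.8% and 15.7%, and mural-like cells at 1.06%, 19.9% and 20.5% in libraries 2 to 4. Endothelial-like cells were at 2.44%, 5.32%, 9.77% and 32%, and macrophage-like cells at 3.39%, 3.75%, 8.22% and 14.2%. Neuron-like cells, which do not divide, were at 2.88% in library 2 (1.72% to 4.52%) and 4.60% in library 3 (3.64% to 5.72%), but Birc5 gave 83.3% and 77.3% of their UMIs of the 5 genes. Their median depths before thinning were 1105 and 42339 UMIs, against 1514.5 and 3235 in the Schwann-like cells. The 5 genes summed to 10.8 and 23.9 CPM in neuron-like cells of libraries 2 and 3, and to 237 and 341 CPM in Schwann-like cells. Without Birc5, a choice made after these values were seen, the neuron-like shares were 0.801% (0.261% to 1.86%) and 0.907% (0.509% to 1.49%) and the Schwann-like shares of libraries 1 to 4 were 3.46%, 3.89%, 11.7% and 17.7%. Without cluster 9 the Schwann-like shares were 0.446%, 2.10%, 5.20% and 7.52%. Thinning left out 81, 673, 194 and 156 Schwann-like cells with under 2000 UMIs in libraries 1 to 4, and 3530 of the 4154 neuron-like cells of library 2. Without thinning the share in library 4 was 33.0%, at a mitochondrial limit of 10% it was 32.4% and with at least 2 UMIs 12.5%. In library 3 it was 7.98% with at least 2 UMIs, and in library 2 it was 6.83% without cluster 13.

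**Figure D2:**
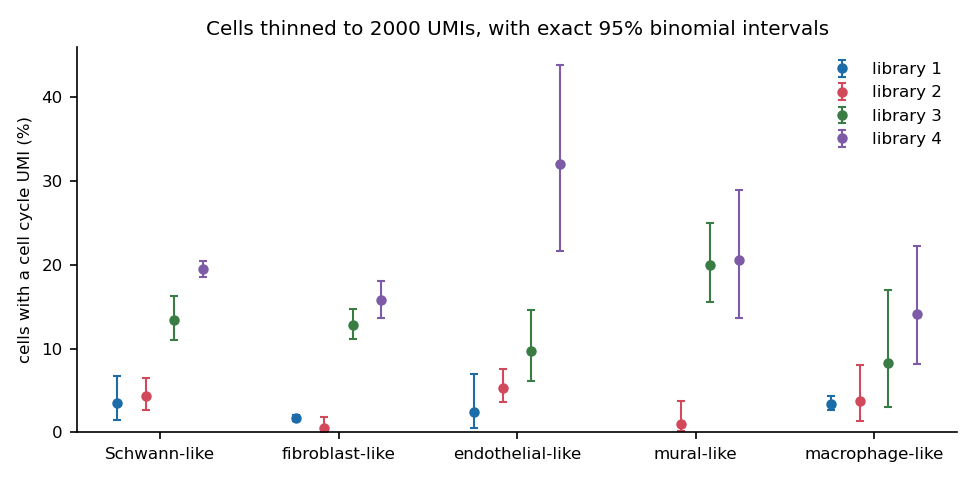
Points give the percent of cells, thinned to 2000 UMIs, with at least 1 UMI of the 5 cell cycle genes, by class (horizontal axis) and library (colour), and bars are exact 95% binomial intervals. Schwann-like cells were at 3.46% and 4.29% in libraries 1 and 2 and at 13.4% and 19.5% in libraries 3 and 4, and mural-like cells of library 1 were too few to be plotted.

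Transcripts of 6 fibroblast markers were also counted in Schwann-like cells. In library 4, the collagen genes Col3a1, Col1a2 and Col1a1 were at 15.4%, 13.1% and 9.74% of their fibroblast-like CPM, and Dcn, Lum and Pdgfra at 0.542%, 0.584% and 0.609%. Endothelial-like cells of library 4 had between 4.32% and 7.55% for all 6 genes. Macrophage-like cells had between 3.98% and 5.44% for 5 of them and 1.21% for Pdgfra. The markers were chosen before the data were examined, and this comparison afterwards.

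**Figure D3:**
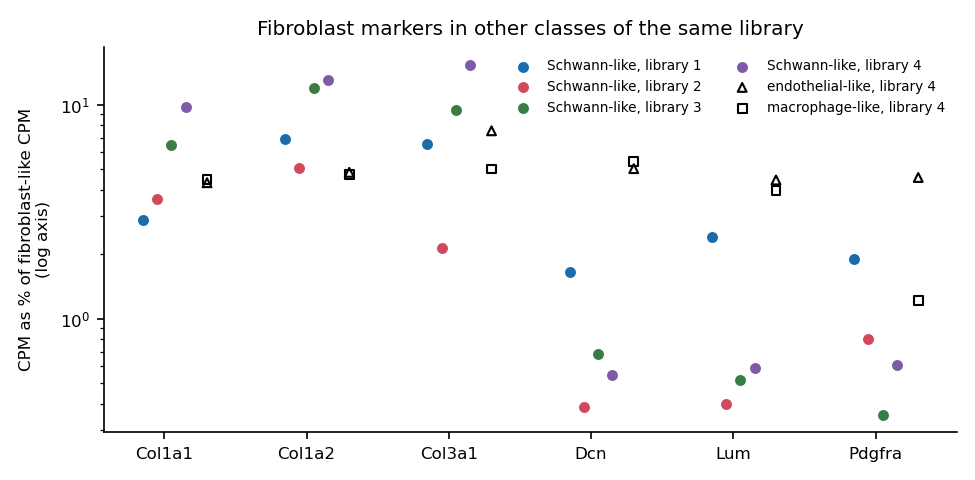
The CPM of each fibroblast marker (horizontal axis) is shown as a percent of its level in fibroblast-like cells of the same library (vertical log axis), for Schwann-like cells of each library (coloured points) and for endothelial-like and macrophage-like cells of library 4 (open symbols). In Schwann-like cells of library 4 the collagens lay at 9.74% to 15.4% and the other 3 markers at 0.542% to 0.609%.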

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

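The haemoglobin comparison was chosen only after the barcodes had been seen. Barcodes with fewer than 500 detected genes, which no comparison at the main setting used, held haemoglobin transcripts as a large part of their UMIs: 45.0% in library 1, 21.4% in library 2, 72.8% in library 3 and 71.9% in library 4. In the cells kept, haemoglobin transcripts made up 0.00965%, 0.166%, 0.724% and 1.03% of UMIs. These barcodes numbered 589, 1171, 3371 and 1750 in libraries 1 to 4.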

How the results depend on the processing

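Removal of the top 6% of doublet scores, the omission of cluster 13, cluster 9 or Birc5, and the 2 other definitions of neuron-like cells were tried only after the data had been seen. Over 20 alternatives and 1119 values, 155 of 156 list medians of Schwann-like over fibroblast-like cells that could be computed kept their sign. So did 591 of 595 gene values of that contrast. These gene values covered only the named genes, picked for large ratios going the same way in every library where they could be measured. Their count therefore does not speak for other genes. In the cluster 10 contrast 125 of 142 list medians kept their sign and in the cluster 6 contrast 116 of 120. In these cluster contrasts, the lists that turned lay inside the central 95% of random lists at the main setting, and the cause was not tested for these or for the values below.

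Schwann-like shares at a mitochondrial limit of 10% were 1.94%, 2.63%, 9.90% and 54.6% in libraries 1 to 4. With 200 genes they were 14.6%, 10.9% and 67.1% in libraries 2 to 4. Library 2 gave 2.85% without cluster 13 and at resolution 0.4, where 99.8% of cluster 13 cells joined the cluster matched to cluster 10. It gave 15.5% with doublets kept and 13% without the top 6% of doublet scores. Without cluster 9, libraries 3 and 4 gave 12.3% and 66.5%. Neuron-like shares of library 2 were 5.07% without its low-depth clusters, 52.5% with the unnamed clusters, 38.4% at a mitochondrial limit of 10%, 51.0% with 200 genes and 50.9% without the top 6% of doublet scores. Those of library 3 were 49.8% with the unnamed clusters, 20.1% at a mitochondrial limit of 10% and 17% with 200 genes.

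Without cluster 9, which was picked for its cell cycle genes, the cell cycle median of Schwann-like over fibroblast-like cells turned to -1.11, Mki67 to -3.08, Top2a to -4.39, Birc5 to -1.66 and Cenpf to -3.08. Chemokines were at -3.68 with a minimum of 100 UMIs and -3.57 with thinned cells. In the cluster 10 contrast, matrix was at 0.84 with the mean of each cell's CPM, cell cycle at -5.39 without cluster 13, -0.54 without cluster 9 and -4.89 at resolution 0.4, and immediate early genes at -0.41 with thinned cells. In the contrast of the Schwann-like cluster of library 4 with the highest myelin level, resolution 0.4 gave 3.49 for myelin, 0.48 for cholesterol synthesis and -0.66 for matrix. A mitochondrial limit of 10% gave 0.77 for cholesterol synthesis, -0.78 for matrix, -0.84 for Hox and -1.07 for immediate early genes. Without cluster 9 cell cycle was at -0.86.

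Cell cycle shares without cluster 9 were 0.446%, 2.10%, 5.20% and 7.52% in libraries 1 to 4. That of library 4 was 17.7% without Birc5. Those of library 2 were 6.83% both without cluster 13 and at resolution 0.4. Library 3 gave 9.38% when thinned to 1000 UMIs and 7.98% with 2 UMIs. Library 4 gave 33.0% unthinned, 15.3% when thinned to 1000 UMIs, 12.5% with 2 UMIs and 32.4% at a mitochondrial limit of 10%.

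No value was obtained for cluster 10 at a mitochondrial limit of 10%, where no cluster matched it, for its Hox list with a minimum of 100 UMIs or thinned cells, or for Psmb8, Olig1, Lif, Hoxb5, Hoxb8 and Hoxd10 under some settings. Alternatives for contrasts between groups were not run, because the barcodes name no samples. Depth limits library 1 most, since its Schwann-like cells held 904784 UMIs and a simulated 2-fold change was recovered for 46.8% of genes.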

Other observations

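The tests of 1 free-RNA pool in clusters 3 and 7 and in clusters 3 and 13, and that of free RNA as the only source of fibroblast transcripts, were chosen only after the results had been seen. That of clusters 3 and 13 took the place of a test on markers that had themselves named cluster 13. Set against macrophage-like cells, Schwann-like cells were far lower in antigen presentation genes in 4 of 4 libraries (list medians from -9.58 to -5.31) and higher in matrix genes (2.78 to 3.97). Cd74, RT1-Da, RT1-Db1, RT1-Ba and RT1-Bb, which serve class II antigen presentation, were highest in macrophage-like cells in every library among 9 such genes. Cd74 reached 20118, 12932, 1973 and 654 CPM there. The macrophage-like class included cluster 20 (559 cells in library 1), led by class II genes such as RT1-Bb and RT1-Da. Its macrophage score was 0.12, against 0.531 to 0.992 in the other macrophage-like clusters, and its part in these levels was not tested. The unnamed cluster 40, which scored highest for B cells, was not ranked. Cxcl2 was highest in macrophage-like, Cxcl12 in endothelial-like and Il33 in fibroblast-like cells, of 12 chemokines and cytokines. Against endothelial-like cells, myelin (4.08 to 5.59) and cholesterol synthesis (2.15 to 2.97) were higher in 4 of 4 libraries and chemokines lower (-3.64 to -1.03). Cxcl12 (-8.67 to -5.40), Efnb2 (-6.50 to -5.28), an arterial signal, and Nrp1 (-7.31 to -3.01) were among the lower genes, with the floor used for Cxcl12 and Efnb2 in at least 1 library, and Col5a3 (3.37 to 5.10) was among the higher.

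Against neuron-like cells, measured in libraries 2 and 3, Schwann-like cells were higher in myelin (7.0 and 8.23 as the lower and higher median), matrix (3.59 and 4.66), regulators (3.64 and 4.23), cell cycle (3.51 and 4.11) and immediate early genes (3.57 and 3.92). Cluster 9 held 91.6% and 92.6% of the Schwann-like UMIs of 5 cell cycle genes in libraries 2 and 3. Fos was at 4.50 and 5.04 and Lama2 at 4.19 and 5.73. Cholesterol synthesis did not separate them (-0.22 and 0.32), with Msmo1 higher in Schwann-like cells (1.02 and 2.15) and Fdft1 lower (-0.65 and -0.49). Against mural-like cells, in libraries 2 to 4, cholesterol synthesis was higher (1.12 to 2.09) and Hox genes were lower (-2.29 to -1.48), with Hoxc10 from -3.17 to -2.51. Col4a1 (-2.61 to -0.47) and Col4a2 (-2.84 to -1.0), chains of basement membrane collagen, were also lower than in mural-like cells.

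In library 2, 2 neuron-like clusters, 3 and 7, held barcodes of low depth, with medians of 902 and 1348 UMIs. One pool of free RNA in both would give 1 mitochondrial share, but that of cluster 7 (7.92% of UMIs) was 4.07 times that of cluster 3 (1.95%), which argues against it. Nuclei, which carry less ribosomal protein RNA, may account for either cluster: the ribosomal protein share relative to the deep clusters of library 2 that scored highest for neurons was 0.887 in cluster 3 and 0.848 in cluster 7, between the bounds of 0.67 and 1 set beforehand, so nuclei and whole cells cannot be told apart by it. The mitochondrial share of these deep clusters was 11.6%, nearer to cluster 7 than to cluster 3, but no bound had been set for it, and nuclei stay open for both. No biological explanation was tested, since the library has no group.

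Cluster 13 of library 2, Schwann-like and of low depth, might hold partial RNA of cells like those of cluster 10. Of 723 genes at least 4-fold apart between clusters 10 and 32, 72.3% had a cluster 13 level nearer to cluster 10, short of the bound of 75% set beforehand and above the 50% that would have excluded it, so this stays open. A pool of free RNA shared by clusters 3 and 13 would keep genes used neither for clustering nor for naming at 1 level. Over 60 such genes of the fixed lists the median size of the log2 ratio between cluster 13 and cluster 3 was 2.20, with 57 intervals away from 0, which argues against it. The median mitochondrial share per cell was 1.504% in cluster 13 and 0.926% in cluster 3. Nuclei, raised above for clusters 3 and 7, were not tested for cluster 13 and stay open. No biological explanation was tested.

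In Schwann-like cells of library 4, 99.9% held at least 1 UMI of the 6 fibroblast markers. Free RNA from fibroblasts as the only source would keep these in 1 ratio, but the highest ratio to the fibroblast level (Col3a1) was 28.4 times the lowest (Dcn), which argues against it. Doublets with fibroblasts as the main source would gather the UMIs in few cells. The 6% of cells with the most held 20.7% of the UMIs, under the bound of 30% set beforehand. This count pooled the 6 markers, and Col3a1 (4001 CPM) and Col1a1 (2633 CPM) far exceeded Col1a2 (37.2 CPM), Dcn (17.4 CPM), Lum (9.07 CPM) and Pdgfra (1.17 CPM). It therefore speaks for Col3a1 and Col1a1, as does the 99.9% above, and cannot tell whether doublets supplied Col1a2, Dcn, Lum or Pdgfra. Transcription of the collagen genes in Schwann-like cells themselves may add to a free-RNA background, and was not tested apart from these values, nor was any explanation from the design. In libraries 1 to 3, Col1a2 was at 6.92%, 5.04% and 12.0% of its fibroblast-like level and Dcn at 1.65%, 0.384% and 0.681%.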
